A study of Mus musculus with 19 samples.

How the data were processed

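RNA was measured in 1 cm2 pieces of skin from female mice of the strain Ptch1+/- K14-CreER2 p53fl/fl, in which tamoxifen removes the floxed Trp53 gene in keratin 14 expressing cells and 1 Ptch1 allele is missing, so that basal cell carcinomas (BCC) form after x-rays. The file holds 19 poly-A libraries from 16 mice, made with a directional kit and oligo dT selection per the labels' protocols. Healthy, not induced skin came from 5 mice (6 libraries), induced skin with early BCC from 4 mice (4 libraries), induced skin after ablative fractional laser (AFL) from 3 mice (4 libraries) and induced skin after topical vismodegib, an inhibitor of the Hedgehog receptor Smoothened, from 4 mice (5 libraries). Per the labels, induction was 3 tamoxifen injections of 300 µg and 1 x-ray dose of 4 Gy. The laser group had 1 treatment at a density of 5% with 40 mJ per microbeam, and the vismodegib group had 8 applications. Skin was harvested on day 4 per the labels. No vehicle-treated or sham-treated mice are among the samples used here.

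The deposited values are RSEM expected counts per gene, not normalised. Per the submitters' processing notes they were made with Bowtie2 and RSEM against GRCm39. Tool versions, the gene annotation, the strand setting of the counting and any filter are not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart with certainty. The file lists 18521 gene symbols, and 3.42% of its values are not whole numbers. Library totals lay between 27185900 and 33556600 counts.

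The expected counts deposited by the authors were rounded to whole numbers, and the libraries of mouse 11 (AFL), mouse 12 (vismodegib) and mouse 16 (healthy), which each had a pair, were summed, so that the replicate was the mouse. The 2 libraries of mouse 16 carry ages of 128 and 135 days in the labels, so its number or an age may be wrong, and the 5 healthy mice rest on the number. The paired libraries of a mouse differed by far more than counting error and were not copies of one another. Genes were filtered with filterByExpr by group in edgeR 4.0.16 (R 4.3.3), which left 15760 genes and removed 2761. Among those left, 6 pairs of symbols carry identical counts in every library, and with each pair counted once 1832 in place of 1834 genes changed in vismodegib against healthy, the largest difference. All 16 mice entered one quasi-likelihood fit with TMM scaling and robust dispersion estimates, with the group as the sole term. The common dispersion was 0.178. Each of 6 contrasts between the groups was tested with edgeR's quasi-likelihood F test, and p-values were adjusted by Benjamini and Hochberg over the 15760 genes. "Rose", "fell" and "changed" refer to genes with an adjusted p under 0.05 in that test. Normalised expression (CPM) uses the TMM-scaled library sizes and is given as the mean ± SD over mice. Log2 fold changes are given with their standard errors (SE). For genes with 3 or fewer counts over a whole group the fitted value depends on the prior count. For these a ratio of scaled counts was used, as a lower bound from a floor of 3 counts over the group where it held none, or with a 95% counting interval where it held 1 to 3. Such intervals and floors cover counting error only, since reads from PCR libraries without molecular identifiers are not independent molecules.

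Before the data were examined, 30 lists with 439 gene symbols were written for Hedgehog signalling and other programmes of skin, tumour, immune cells and neighbouring tissues. Of these, 427 are in the file (1 through a synonym, Il36a as Il1f6, in the GRCm38.p6 RefSeq gene table, used for names alone) and 414 were tested. A list was called where camera in limma 3.58.1, with its preset correlation of 0.01 between genes, gave an adjusted p under 0.05 over the lists of one comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. For every list the members that changed are counted over all genes tested and also adjusted over the list alone.

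The genes named were set by a rule written before the data were examined. It takes Trp53, Ptch1, Gli1, Gli2 and Hhip in every comparison. For the 3 comparisons of BCC with healthy skin and of each treatment with BCC, it takes the 5 largest rises and the 5 largest falls among genes with an adjusted p under 0.05, at least 1 CPM in the higher group, no overlap between the mice of both groups and a symbol that is not a clone or predicted name. Of each list that was called or held a changed gene, it takes the 2 members with the smallest p, or 3 for the Hedgehog, embryonic follicle and BCC, wound keratinocyte and T cell lists. A gene named outside the rule is given as chosen after its values were seen. Not every gene that the rule takes is reported.

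Alternatives were DESeq2 1.42.0, RLE scaling, library size alone, no low-count filter, a filter of 1 CPM in 3 mice, all 19 libraries as replicates, limma voom with the mouse as a random effect, 1 library per mouse, a fit of the 2 groups alone, the replicate number as a block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, days since induction as a covariate among induced mice, and leaving out each mouse in turn. Alternatives added after the data were seen were a covariate for the expression of growing-hair genes and a fit without the 2 induced mice that expressed them. The correlation of treatment effects that share the BCC mice was set beside 20 simulated data sets without effects and beside 6 splits of the BCC mice. Other splits of the mice of each comparison were counted, with at most 100 per comparison. Permutation tests of list members used 100000 draws, and spreads of list medians came from 10000 bootstrap draws of the members. Both leave out the spread between mice.

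The procedure was tested on simulated data drawn from the means and library sizes of these mice, with 100 genes changed 2-fold and 100 changed 4-fold. In BCC against healthy, over 15656 simulated genes, 12% of the 2-fold and 81% of the 4-fold changes were recovered, with 0 false calls. In AFL against BCC, over 15659 genes, 4% and 63% were recovered with 3 false calls. In vismodegib against BCC, over 15645 genes, 9% and 67% were recovered with 2 false calls. In AFL against vismodegib, over 15656 genes, 11% and 65% were recovered with 5 false calls. A shifted list was called and 0 of 20 unshifted lists were. The simulated genes were drawn independently of one another, so this does not test calls of lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

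Genomic coordinates were not used here, because the reference at hand was GRCm38. Splicing and allele-specific expression were not analysed here.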

Results

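Gene expression was measured in 19 skin libraries from 16 female mice, with 5 healthy mice, 4 mice with early BCC, 3 with BCC treated by AFL and 4 with BCC treated by vismodegib. Library totals lay between 27185900 and 33556600 expected counts. Healthy mice were 128 to 137 days old and induced mice 228 to 326 days old, so age and induction changed together. Days since induction were 130 to 144 in the BCC group, 80 to 126 after AFL and 109 to 137 after vismodegib. Values are means over mice with their SD, and n is the number of mice.

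The engineered genes came first. Trp53, the floxed gene, had 119 ± 17.8 CPM in healthy skin (n = 5), 29.8 ± 5.4 in BCC (n = 4), 38.9 ± 6.84 after AFL (n = 3) and 40.1 ± 16.3 after vismodegib (n = 4). Its level was lower than in healthy skin in every induced group. Log2 fold changes were -2.01 (SE 0.26, adjusted p = 0.000423) in BCC, -1.62 (SE 0.28, adjusted p = 0.00126) after AFL and -1.57 (SE 0.25, adjusted p = 0.00112) after vismodegib. Whole skin also holds cells without keratin 14, in which the gene stays intact. Ptch1 encodes the Hedgehog receptor and is itself a Hedgehog target, and the strain carries 1 working allele. It had 64.3 ± 21.4 CPM in healthy skin, 104 ± 26.1 in BCC, 43.4 ± 28.7 after AFL and 47.7 ± 22.2 after vismodegib. None of its 6 contrasts passed.

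The comparison of BCC with healthy skin asked what tumour induction changed. Trp53 fell to a log2 fold change of -2.01, and Ptch1 stood at 0.70 (SE 0.39, adjusted p = 0.447). Hhip, a Hedgehog-binding protein that the pathway itself switches on, rose 11.5-fold, from 8.89 ± 3.32 CPM (n = 5) to 102 ± 58.4 (n = 4; log2 fold change 3.52, SE 0.49, adjusted p = 0.000775). Gli2, a transcription factor of the pathway, rose from 48.3 ± 7.6 to 117 ± 21.8 CPM (1.27, SE 0.29, adjusted p = 0.0209). Gli1, its best known target, was at 94.7 ± 32.2 and 295 ± 25.4 CPM and did not pass (1.64, SE 0.43, adjusted p = 0.052). The whole Hedgehog list of 10 genes had a median of 1.04 and was called (camera adjusted p = 1.71e-06), but not with an estimated correlation (adjusted p = 0.439) or in fry (adjusted p = 0.0856). Of its members 2 rose and 0 fell over all genes, and 6 rose adjusted over the list alone. Hhip kept its call under all alternatives tried. That of Gli2 ended without healthy mouse 14 (1.28) or 15 (1.18), without BCC mouse 4 (1.30) or 8 (1.25) and under the replicate block (1.26). It ended as well in limma voom (1.32, adjusted p = 0.148) and with 1 library per mouse (adjusted p = 0.0638).

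**Figure D1:**
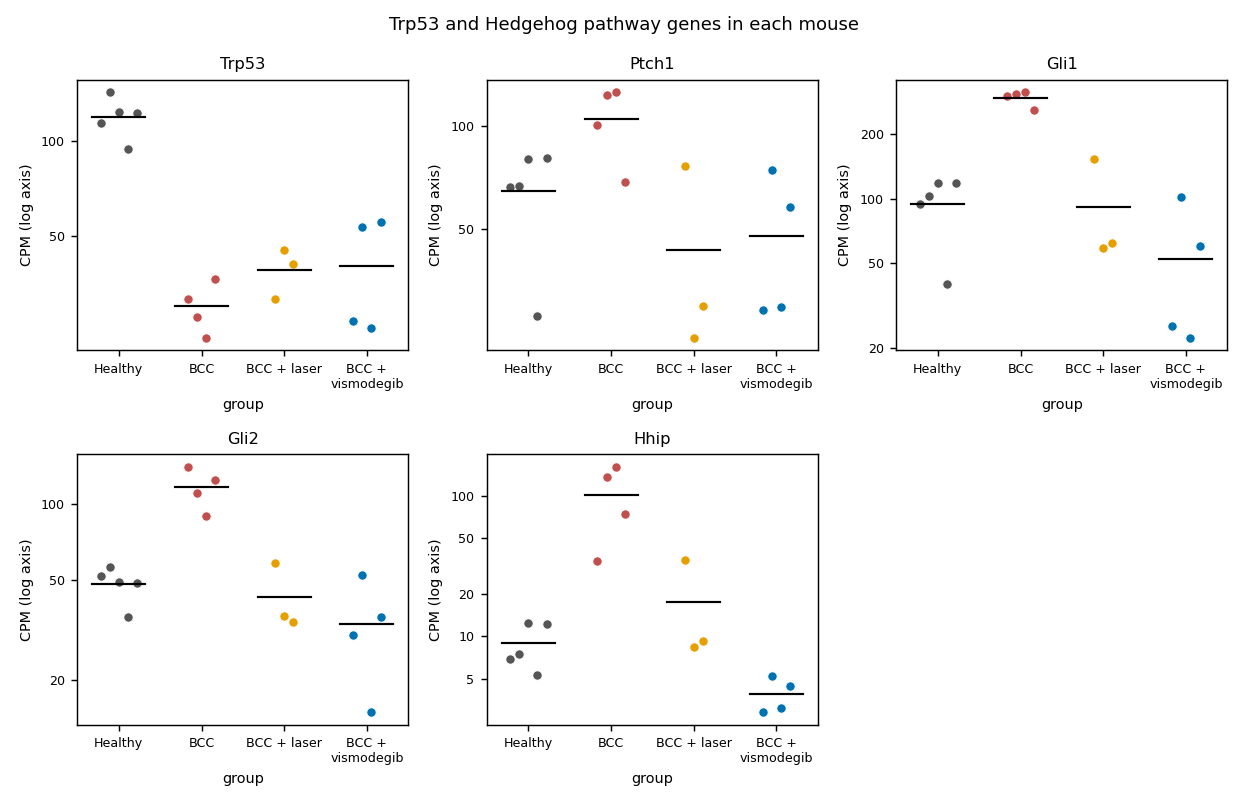
CPM of Trp53, Ptch1, Gli1, Gli2 and Hhip in each mouse on a log axis, by group, with a line at the group mean. Trp53 lies lower in all induced groups than in healthy skin, and mean Gli1 is 295 CPM in BCC against 94.7, 91.3 and 52.2 CPM in healthy, AFL and vismodegib skin.

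Of 15760 genes tested, 445 changed, 420 up and 25 down, and 431 of them by at least 2-fold. The 5 largest rises included regulators of forebrain and eye development. Six3 held no counts in healthy skin and was at least 98.9-fold higher in BCC (adjusted p = 0.0084), or 55.8-fold without BCC mouse 8. Vax1 rose from 0.0256 to 3.93 ± 0.786 CPM (7.14, SE 0.54, adjusted p = 6.93e-06), and Barhl2 had a ratio of 125 with a counting interval of 42.3 to 611, and of 50.3 without BCC mouse 4. Lce3e of the late cornified envelope (7.24, SE 0.86) and the matrix protease gene Mmp10 (7.03, SE 1.13) completed this group. The largest falls were Mtarc1, for a mitochondrial reductase (-2.86, SE 0.58), the sialidase gene Neu2 (-2.16, SE 0.51), Trp53, the secreted glycoprotein gene Lrg1 (-1.74, SE 0.40) and Gchfr, a regulator of biopterin synthesis (-1.57, SE 0.38). Of these falls, Mtarc1 lost its call without BCC mouse 4 (-2.79). Neu2 lost it without any of healthy mice 15 and 16 and BCC mice 3, 4 and 5 (-2.28 to -1.84). Lrg1 lost it without any of healthy mice 13, 15 and 16 and BCC mice 4, 5 and 8 (-1.81 to -1.51), and Gchfr lost it without any of healthy mice 13 to 16 and BCC mice 4, 5 and 8 (-1.65 to -1.37). With the mouse as a random effect in limma voom, the calls of Mmp10 (6.21), Mtarc1 (-2.62) and Neu2 (-1.94) ended as well. The replicate block ended those of Mtarc1 (-2.25), Neu2 (-1.86), Lrg1 (-1.61) and Gchfr (-1.42), and library size alone that of Gchfr (-1.5).

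In the wound keratinocyte list 6 of 20 genes rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.80 (camera adjusted p = 5.73e-07; adjusted p = 0.439 with an estimated correlation). Krt6b, a keratin of wounded skin, rose from 2.22 ± 2.18 to 229 ± 187 CPM (6.68, SE 0.95, adjusted p = 0.000845). Il1f6, which encodes interleukin 36 alpha, rose 20.8-fold (4.38, SE 0.55), and the cornified envelope gene Sprr2d rose by 4.19 (SE 0.63). In the matrix list of 21 genes 4 rose and 0 fell (5 and 1 adjusted over the list alone), Mmp10 and the collagenase gene Mmp13 (4.99, SE 0.71) among them, beside Postn and Mmp14, named after their values were seen. Its median was 0.86 (camera adjusted p = 0.000104; adjusted p = 0.571 with an estimated correlation). Without BCC mouse 4 the matrix median was 0.40. The basal keratinocyte list had a median of 0.41 (camera adjusted p = 0.00376; adjusted p = 0.439 with an estimated correlation). Its laminin genes Lamb3 (1.42, SE 0.26) and Lama3 (1.37, SE 0.29) rose, the latter without a call when BCC mouse 4 was left out (1.29) or under the replicate block (1.34). The embryonic follicle and BCC list stood at 0.57 (camera adjusted p = 0.00741; adjusted p = 0.571 with an estimated correlation). That call ended without healthy mouse 16 (0.48) or BCC mouse 3 (0.54) and under the replicate block (0.49). Its member Lhx2, a follicle stem cell factor, rose by 1.53 (SE 0.31, adjusted p = 0.00985), without a call in limma voom (1.54).

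Other lists were called with no member past the threshold. Growing hair follicle genes had a median of -2.06 (camera adjusted p = 1.71e-06) and melanocyte genes of -1.62 (camera adjusted p = 0.000566), with the hair factor Foxn1 at -1.28 and the pigment cell gene Mlana at -1.96. The mice differed in hair phase. The mean log2 CPM of the growing-hair genes was 8.11 in BCC mouse 3 and between 0.64 and 2.66 in the other BCC mice. It was between 3.55 and 9.25 in the healthy mice. Over all 16 mice this score correlated at r = 0.975 with the first principal component. That component held 59.0% of the variance of the 1000 most variable genes. Without mouse 3 the medians were -6.55 and -6.84, and under the replicate block -3.35 and -3.16. Adipocyte genes (median -1.40, camera adjusted p = 5.17e-06; Plin1 -2.09) and muscle genes (-1.48, camera adjusted p = 5.17e-06; Acta1 -2.34) were lower as lists. So were macrophage genes (-0.63, camera adjusted p = 0.00356; Cd68 -0.89) and resident fibroblast genes (-0.57, camera adjusted p = 0.00999; Pi16 -1.18). Interferon genes (0.58, camera adjusted p = 0.000733; Oas3 1.67), inflammatory cytokine genes (1.16, camera adjusted p = 0.00121; Cxcl2 2.87) and regulatory and checkpoint genes (0.35, camera adjusted p = 0.0396; Entpd1 0.81) were higher. With an estimated correlation the adjusted p was 0.596 for the regulatory and checkpoint list and 0.571 for each of the other lists of this paragraph. Fry ended all 14 list calls of this comparison. The macrophage and fibroblast calls ended without BCC mouse 3 (-0.46 and -0.43), the latter also without healthy mouse 16 (-0.49). The regulatory and checkpoint call ended without healthy mouse 10, 13 or 14 or BCC mouse 5 or 8 (0.20 to 0.31) and with all 19 libraries as replicates (0.26). Without healthy mouse 15 the regulatory and checkpoint median was 0.60 and the macrophage median -0.40. With growing-hair expression as a covariate, chosen after the data were seen, the Hedgehog median was 1.59 and the embryonic follicle median 0.97. The interferon (0.32), regulatory and checkpoint (0.004328) and growing hair calls (-0.16) ended with it. It moved the matrix (0.48), fibroblast (-1.14), macrophage (-1.0), adipocyte (-2.21) and muscle medians (-2.56). Apart from BCC mouse 3, the BCC mice had lower growing-hair scores than every healthy mouse. Hair phase and induction are therefore largely confounded, and the covariate cannot separate them.

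Among lists that were not called, Cd5 of T cells rose by 1.15 (SE 0.26, adjusted p = 0.0196; T cell list median 0.37) and the IgE receptor gene Fcer1a by 2.73 (SE 0.60, adjusted p = 0.0179; mast cell list -0.36). Cd5 lost its call without healthy mouse 13, 14 or 16 or BCC mouse 4 (1.08 to 1.16) and under the replicate block (1.13), and Fcer1a without healthy mouse 13 or 14 or BCC mouse 4 or 5 (2.49 to 2.62). Medians were -0.20 for Wnt targets, -0.14 for the cell cycle, 0.33 for differentiated keratinocytes, 0.69 for neutrophils, -0.39 for dendritic cells, 0.03 for cytotoxic cells and 0.10 for B and plasma cells. They were -0.09 for antigen presentation, -0.38 for endothelium, 0.20 for sebaceous gland, -0.48 for erythroid cells, -0.14 for heat shock and -0.25 for immediate early genes. The p53 target list had a median of 0.04 with a mean of -0.05, and its test pointed down without a call (camera adjusted p = 0.352).

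The comparison of AFL with BCC asked what the laser changed in induced skin. Trp53 stood at 0.39 (adjusted p = 0.471) and Ptch1 at -1.26 (adjusted p = 0.113). Hhip fell from 102 ± 58.4 CPM (n = 4) to 17.4 ± 15 (n = 3; -2.55, SE 0.58, adjusted p = 0.0112) and Gli2 from 117 ± 21.8 to 42.8 ± 13.7 (-1.45, SE 0.34, adjusted p = 0.0136). Gli1 did not pass (-1.69, SE 0.51, adjusted p = 0.055). The Hedgehog list had a median of -1.57 (camera adjusted p = 4.64e-07; adjusted p = 0.2 with an estimated correlation). It held 3 genes that fell and 0 that rose, or 8 that fell adjusted over the list alone. The third was the cyclin gene Ccnd1 (-1.18, SE 0.32, adjusted p = 0.0347). The laser mice had fewer days since induction, and with days as a covariate the calls ended for Hhip (-1.56, adjusted p = 0.286) and Gli2 (-1.5, adjusted p = 0.148). Both also ended without AFL mouse 7 (-2.22 and -1.34) or 11 (-2.29 and -1.34), and that of Gli2 in limma voom (adjusted p = 0.0658). The call of Ccnd1 ended without BCC mouse 3 or 4 or any AFL mouse (-1.35 to -1.05).

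In all, 1221 genes changed after AFL, 961 up and 260 down. Interferon-stimulated and macrophage genes gave the firmest rise. In the interferon list 23 of 26 genes rose and 0 fell (25 rose adjusted over the list alone), with a median of 3.31 (camera adjusted p = 3.84e-58). The call held with an estimated correlation (adjusted p = 0.00361). Mx1, an antiviral effector, rose from 2.6 ± 0.696 to 54.5 ± 4.18 CPM (4.39, SE 0.42, adjusted p = 2.2e-05), and Irf7, the transcription factor that amplifies interferon production, rose by 3.75 (SE 0.37). In the macrophage list 14 of 16 genes rose and 0 fell (15 rose adjusted over the list alone), with a median of 2.57 (camera adjusted p = 2.02e-29, or 0.0088 with an estimated correlation). Cd68 rose from 28.8 ± 4.14 to 331 ± 26.7 CPM (3.52, SE 0.31, adjusted p = 9.41e-06) and the Fc receptor gene Fcgr1 rose 45.4-fold (5.50, SE 0.45, adjusted p = 9.36e-06).

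Neutrophil genes had a median of 5.21, with 7 of 10 up and 0 down (8 up adjusted over the list alone; camera adjusted p = 2.86e-08; adjusted p = 0.2 with an estimated correlation). The growth factor receptor gene Csf3r was among those up (4.80, SE 0.59, adjusted p = 9.86e-05). Inflammatory cytokine genes had a median of 4.00, with 14 of 17 up and 0 down (16 up adjusted over the list alone; camera adjusted p = 2.26e-10; adjusted p = 0.218 with an estimated correlation). Osm (4.93, SE 0.66) and the chemokine gene Ccl3 (6.96, SE 1.08) were among them. Cytotoxic cell genes rose in 4 of the list's members (6 adjusted over the list alone; median 1.81, camera adjusted p = 0.000312; adjusted p = 0.282 with an estimated correlation). Gzma, for a granule protease, was at 5.96 (SE 0.90) and the natural killer cell receptor Ncr1 at 3.27 (SE 0.62), and the rest of the 4 were Gzmb and Fasl, named after their values were seen. Mast cell genes (median 0.97, camera adjusted p = 9.17e-05; adjusted p = 0.2 with an estimated correlation) rose in 4 members. Tpsab1 rose by 3.73 (SE 0.31) and Hdc by 4.22 (SE 0.69), with Cma1 and Tpsb2 named after their values were seen. Dendritic cell genes (0.51, camera adjusted p = 0.0124; adjusted p = 0.484 with an estimated correlation) rose in 3 members. These were Clec10a (2.05, SE 0.36), Siglech (3.45, SE 0.63) and Itgax, the last chosen after its values were seen. The T cell list had a median of -0.46, a mean of 0.01 and a test that pointed down without a call (adjusted p = 0.8). Single genes rose in the lists of regulatory and checkpoint genes (Il10, 3.24, SE 0.75; list median 0.68) and B cells (Cd79b, 2.79, SE 0.57; list median 0.78). Without AFL mouse 11 the inflammatory median was 2.31, and the values were 3.26 for Osm, 4.32 for Ccl3 and 2.27 for Hdc. Without AFL mouse 7 the dendritic call ended (0.32) and the cytotoxic median was 1.14. The cytotoxic call ended with a filter of 1 CPM in 3 mice (0.71, adjusted p = 0.135). Without AFL mouse 2 the mast cell median was 0.55.

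**Figure D2:**
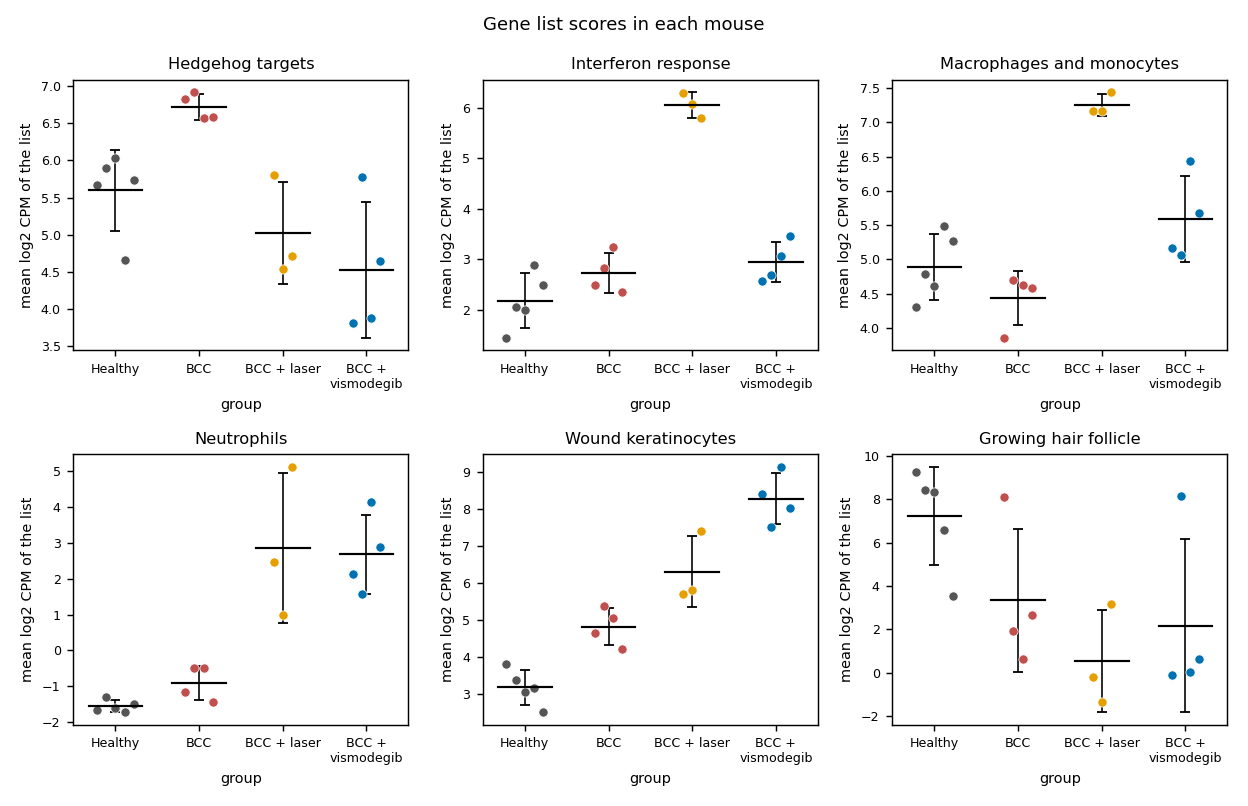
Mean log2 CPM of the genes of 6 lists in each mouse, by group, with a line at the group mean and bars for the SD. The interferon and macrophage scores of the 3 AFL mice lie above those of every other mouse, while growing-hair scores range from 0.64 to 8.11 among the BCC mice.

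The matrix list had a median of 1.29, with 7 of 21 genes up and 0 down (14 up adjusted over the list alone; camera adjusted p = 2.26e-10; adjusted p = 0.2 with an estimated correlation). Examples are Thbs2 (2.09, SE 0.37) and the crosslinking enzyme Loxl2 (1.59, SE 0.30). Endothelial genes rose in 5 of the list's members (8 adjusted over the list alone; median 1.25, camera adjusted p = 3.64e-06; adjusted p = 0.282 with an estimated correlation). Pecam1 was at 1.74 (SE 0.35) and Cdh5 at 1.93 (SE 0.44), and Tie1, Egfl7 and Esam, named after their values were seen, rose too. In the wound keratinocyte list 6 of 20 genes rose and 0 fell (10 and 1 adjusted over the list alone; median 1.58, camera adjusted p = 3.64e-06; adjusted p = 0.256 with an estimated correlation). Among them were the urokinase receptor gene Plaur (3.09, SE 0.44) and the integrin gene Itga5 (1.33, SE 0.29). Erythroid genes had a median of 2.59 (camera adjusted p = 0.00218; adjusted p = 0.2 with an estimated correlation). Its 3 rises were Hba-a1 (2.85, SE 0.51), Alas2 (2.39, SE 0.53) and, chosen after its values were seen, Hba-a2. The early response gene Atf3 rose by 2.46 (SE 0.47) in an immediate early list that was not called (0.41). Without AFL mouse 11 the wound median was 0.75, Plaur stood at 2.01 and the call of Itga5 ended (1.2). Without AFL mouse 7 the endothelial median was 0.82 and the call of Cdh5 ended (1.52). Without AFL mouse 2 that of Alas2 ended (1.76).

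Of the 5 largest rises after AFL, 3 were genes of forming muscle. Actc1, the actin of embryonic muscle, rose by 10.40 (SE 1.43, adjusted p = 0.00028) and the embryonic myosin gene Myh3 by 9.81 (SE 1.25), from 0.137 to 127 ± 100 CPM. Mymk, needed for myoblast fusion (7.62, SE 1.02), rose together with the granulocyte factor Csf3 (7.69, SE 1.5) and the formyl peptide receptor Fpr1 of phagocytes (7.60, SE 1.21). The call of Csf3 ended without AFL mouse 11 (3.37), in limma voom (5.38) and in the fit of the 2 groups alone (7.67). Without AFL mouse 11 Fpr1 was at 5.01. The list of adult muscle genes did not follow, with a median of 0.25 and a mean of 0.37 while its test pointed down (adjusted p = 0.809). The largest falls were Barhl2 (-3.97, SE 0.99), the bone signalling inhibitor Sost (-3.63, SE 1.07), the cartilage proteoglycan gene Acan (-3.40, SE 0.98), Epha8 (-3.27, SE 0.77) and the lens crystallin gene Cryaa (-3.17, SE 0.72). In limma voom the calls of Acan (-3.56) and Epha8 (-3.33) ended, and with library size alone or 1 library per mouse those of Sost (-3.77 and -3.65) and Acan (-3.51 and -3.41). That of Acan also ended under the replicate block (-2.96). Each of these 5 falls lost its call without AFL mouse 7 or 11 (-3.69 and -3.56 for Barhl2, -3.19 and -2.89 for Epha8, -2.79 and -2.86 for Cryaa). Acan lost it also without BCC mouse 3, 4 or 8 (range over mice -3.57 to -2.93), Barhl2 without BCC mouse 4 (-2.65) and in the fit of the 2 groups alone (adjusted p = 0.0507) and Sost without any of the 7 mice (-4.17 to -3.26).

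The embryonic follicle and BCC list had a median of -1.25 (camera adjusted p = 0.00116; adjusted p = 0.282 with an estimated correlation), with 4 genes down and 1 up (5 and 1 adjusted over the list alone). Lhx2 fell by 2.07 (SE 0.38, adjusted p = 0.00232) and the placental cadherin gene Cdh3 by 1.71 (SE 0.44), while the matrix gene Tnc rose by 2.48 (SE 0.45). Sox9 and Epcam also fell, named after their values were seen. The Wnt target list (-0.90, camera adjusted p = 0.000488; adjusted p = 0.282 with an estimated correlation) held no changed member. Growing hair genes had a median of -4.17 (camera adjusted p = 0.00116; adjusted p = 0.703 with an estimated correlation), a call that rested on BCC mouse 3, without which the median was 0.10. Without AFL mouse 11 it was -7.60. The Cdh3 call ended without BCC mouse 3 or any AFL mouse (-1.89 to -1.33). With days since induction as a covariate the calls also ended for Lhx2 (-1.84), Cdh3 (-1.92), Ccnd1 (-1.22), Ncr1 (2.95), Il10 (4.13), Pecam1 (1.09), Cdh5 (1.10), Alas2 (2.57), Itga5 (0.83) and the 5 genes with the largest falls, Barhl2 (-3.32), Sost (-2.70), Acan (-1.71), Epha8 (-2.68) and Cryaa (-1.99). They ended too for the embryonic follicle (-0.96), growing hair (-3.14), dendritic (0.22) and endothelial lists (0.52), and Mymk was at 4.88. Days moved the median of cytotoxic genes to 0.82 (adjusted p = 0.0498), of mast cell genes to 1.71 and of Wnt targets to -1.55. In limma voom the calls of Ccnd1 (-1.17), Cdh3 (-1.58) and Ncr1 (2.79) ended. The growing-hair covariate, added after the data were seen, ended the calls of Ccnd1 (-1.01) and of the dendritic (0.25) and growing hair lists (0.13). It moved the cytotoxic median to 1.03, the mast cell median to 0.57 and the embryonic follicle median to -0.77. Lists that were not called had medians of 0.27 (cell cycle), 0.13 (p53 targets), -4.43 (melanocytes), -0.44 (basal keratinocytes), 0.32 (differentiated keratinocytes), 0.43 (antigen presentation), 0.35 (fibroblasts), 0.71 (adipocytes) and -0.21 (sebaceous gland). The heat shock median was 0.02 with a mean of -0.04 and a test that pointed down.

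The comparison of vismodegib with BCC asked what the Hedgehog inhibitor changed. Trp53 stood at 0.43 (adjusted p = 0.26) and Ptch1 at -1.13 (adjusted p = 0.0706). Gli1, Gli2 and Hhip fell. Gli1 went from 295 ± 25.4 CPM (n = 4) to 52.2 ± 36.9 (n = 4; -2.50, SE 0.48, adjusted p = 0.00294) and Gli2 to 33.3 ± 15.5 (-1.81, SE 0.31, adjusted p = 0.0017). Hhip went to 3.88 ± 1.09 (-4.71, SE 0.57, adjusted p = 0.000207). In the Hedgehog list 7 of 10 genes fell and 0 rose (8 fell adjusted over the list alone), with a median of -1.55 (camera adjusted p = 7.57e-08; adjusted p = 0.351 with an estimated correlation). Without vismodegib mouse 6, in growing-hair phase, the median was -2.58.

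A total of 2684 genes changed, 1266 up and 1418 down. With library size alone in place of TMM, which moved the median of all genes from 0.05 to -0.30, 440 rose and 2164 fell. Among the 5 largest rises, Serpinb3d, a serine protease inhibitor gene, was at least 59.6-fold higher (adjusted p = 0.00863), or 12.4-fold without vismodegib mouse 9, and Sprr2b, a cornified envelope gene, rose from 0.932 ± 0.437 to 444 ± 272 CPM (8.89, SE 0.79, adjusted p = 4.13e-05). S100a9 (7.91, SE 1.45), Saa3 (7.87, SE 1.5) and S100a8 (7.70, SE 1.44), alarmins and an acute phase gene, varied widely between mice. The largest falls were the photopigment gene Opn4 (at least 50.5-fold lower), Barhl2 (ratio 87.0 lower, counting interval 29.4 to 425, and 35.0 without BCC mouse 4), the cholecystokinin receptor gene Cckar (-5.90, SE 0.86), Hamp2 of the hepcidin family (-5.51, SE 1.46) and the zinc finger gene Zscan10 (-5.50, SE 1.09). The call of Hamp2 ended without BCC mouse 8 (-4.75) or vismodegib mouse 9 (-5.31) or 12 (-5.00), in limma voom (-5.39) and under the replicate block (-5.26).

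In the wound keratinocyte list 14 of 20 genes rose and 0 fell (15 rose adjusted over the list alone), with a median of 3.25 (camera adjusted p = 2.82e-14; adjusted p = 0.229 with an estimated correlation). Sprr2d rose 137-fold (7.10, SE 0.76), the wound keratin Krt16 25.1-fold (4.65, SE 0.62) and the iron-binding Lcn2 38.3-fold (5.26, SE 0.71, adjusted p = 0.000389). Sprr2, Lce3 and Serpinb3 genes, like the Hba-a and Hspa1 genes, have near-identical copies between which the counting could split reads, so the values of single members are uncertain. Differentiated keratinocyte genes had a median of 0.69 (camera adjusted p = 0.0264; adjusted p = 0.824 with an estimated correlation). They held 5 rises against 0 falls, such as Casp14 (1.88, SE 0.34) and the desquamation protease gene Klk7 (1.15, SE 0.26), with Krt1, Krtdap and Tgm3 named after their values were seen. This list call ended without BCC mouse 3 (0.72) or 4 (0.59) or vismodegib mouse 1 (0.45) or 12 (0.62). It ended too with the hair covariate (0.45) and with days as a covariate (0.20). With library size alone the values were 0.36 for the list and 0.74 for Klk7, whose call ended in the fit of the 2 groups alone (1.11). The basal keratinocyte list was not called (-0.13, adjusted p = 0.795) and went both ways, with Krt14 up by 2.10 (SE 0.40) and Lamb3 down (-1.0, SE 0.27), the latter without a call when BCC mouse 8 (-0.95) or both mice in growing-hair phase (-0.85) were left out.

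Neutrophil genes had a median of 4.35, with 9 of 10 up and 0 down (9 up adjusted over the list alone; camera adjusted p = 1.5e-07; adjusted p = 0.351 with an estimated correlation). Csf3r (4.53, SE 0.57) and Cxcr2 (4.27, SE 0.76) were among them. In the inflammatory cytokine list 7 of 17 rose and 0 fell (10 rose adjusted over the list alone; median 2.00, camera adjusted p = 1.69e-06; adjusted p = 0.505 with an estimated correlation). Il17a, the interleukin that recruits neutrophils to epithelia, had a ratio of 120 with a counting interval of 40.7 to 583 (adjusted p = 0.000389; ratio 76.9 without vismodegib mouse 9), and the neutrophil chemokine gene Cxcl1 rose by 4.23 (SE 0.85). Macrophage genes had a median of 1.26, with 8 of 16 up and 0 down (10 up adjusted over the list alone; camera adjusted p = 1.18e-05; adjusted p = 0.482 with an estimated correlation). Fcgr1 was at 2.35 (SE 0.39) and Cd68 at 1.11 (SE 0.27). Mast cell genes (0.86, camera adjusted p = 0.0312; adjusted p = 0.81 with an estimated correlation) included Tpsab1, up by 1.51 (SE 0.29). The interferon list stood at 0.32 (adjusted p = 0.458). Lists of dendritic cells (0.07), T cells (-0.07), regulatory and checkpoint genes (0.74), B and plasma cells (-0.25) and antigen presentation (-0.11) were not called. The cytotoxic cell median of 0.05 and mean of 0.11 went with a test that pointed down (adjusted p = 0.795). Without vismodegib mouse 9, whose 100 most abundant genes took 34.5% of counts, the medians were 1.27 for inflammatory and 0.73 for macrophage genes and the mast cell call ended (0.55). It also ended without BCC mouse 3 (0.73) or vismodegib mouse 12 (0.80) and with the hair covariate (0.63). With days as a covariate the inflammatory median was 3.01. Library size alone ended the call of Cd68 (0.74) and gave medians of 0.73 for macrophage and 0.35 for mast cell genes.

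The matrix list had a median of -0.89 (camera adjusted p = 0.0103; adjusted p = 0.824 with an estimated correlation), with 6 genes down and 2 up (7 and 2 adjusted over the list alone). Col1a1 fell by 2.80 (SE 0.55, adjusted p = 0.00368) and the membrane protease gene Mmp14 by 1.2 (SE 0.23), while Timp1 and Mmp3, named after their values were seen, rose. This call ended without BCC mouse 4 (-0.48) or vismodegib mouse 1 (-0.67). The embryonic follicle and BCC list stood at -0.62 (camera adjusted p = 0.00124; adjusted p = 0.482 with an estimated correlation), with 5 genes down and 1 up (6 and 1 adjusted over the list alone). Lhx2 fell by 2.47 (SE 0.34), the stem cell receptor gene Lgr5 by 1.88 (SE 0.43) and Sostdc1 by 1.41 (SE 0.27). Named after their values were seen, Sox9 and Wif1 fell and Tnc rose. Its median was -1.58 without vismodegib mouse 6, -0.35 without mouse 9 and -0.95 under the replicate block. With days since induction as a covariate the calls of Lgr5 (-1.53) and of the matrix list (-0.55) ended. Wnt targets had a median of -0.46 (adjusted p = 0.0687).

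Cell cycle genes had a median of 0.78 (camera adjusted p = 0.000797; adjusted p = 0.824 with an estimated correlation) with no member past the threshold, Cdk1 being at 1.28 (adjusted p = 0.0874), and a median of 0.51 without vismodegib mouse 9. Heat shock genes (0.65, camera adjusted p = 0.0104; adjusted p = 0.351 with an estimated correlation) rose in 3 members, Hspd1 (1.28, SE 0.28), Hspa8 (1.01, SE 0.24) and, named after its values were seen, Hsph1, with a median of 0.39 without vismodegib mouse 9. Library size alone gave medians of 0.42 for the cell cycle and 0.30 for heat shock, and the call of Hspa8 ended with it (0.63) and without BCC mouse 8 (0.88). In the fit of the 2 groups alone those of Hspd1 (1.25) and Hspa8 (0.98) ended, and with library size alone Hspd1 was at 0.82. Sebaceous gland genes (0.88, adjusted p = 0.127) were not called, while Elovl3, a sebaceous fatty acid elongase gene, rose by 2.19 (SE 0.46). The p53 targets were not called either (0.27, adjusted p = 0.648), and the proapoptotic Bbc3 fell by 1.31 (SE 0.28). Medians of the other lists were -0.03 for growing hair, -0.11 for fibroblasts, 0.38 for endothelium, 0.41 for adipocytes, 0.76 for muscle, -0.22 for erythroid cells and 0.13 for immediate early genes, none called. The melanocyte list had a median of -0.18 and a mean of -0.10 with a test that pointed up.

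The direct comparison of AFL with vismodegib asked where the 2 treatments differed. Trp53 (-0.04), Ptch1 (-0.14), Gli1 (0.81) and Gli2 (0.36) did not pass. Hhip was higher after AFL (2.16, SE 0.54, adjusted p = 0.0205), without a call when AFL mouse 2 (1.22) or vismodegib mouse 1 (2.04) was left out. The call also ended in limma voom (1.95, adjusted p = 0.17), with 1 library per mouse (adjusted p = 0.0555), in the fit of the 2 groups alone (adjusted p = 0.0641) and under the replicate block (2.09). The Hedgehog list had a median of 0.12 (adjusted p = 0.404). Here 1442 genes changed, 1054 higher and 388 lower after AFL, or 1366 and 194 with library size alone. Interferon genes were higher after AFL, 23 of 26 over all genes and 23 adjusted over the list alone (median 3.07, camera adjusted p = 2.72e-48, or 0.0104 with an estimated correlation). Irf7 was at 4.00 (SE 0.37, adjusted p = 8.09e-05) and Xaf1 at 2.53 (SE 0.28). Matrix genes followed, with 16 of 21 higher (18 adjusted over the list alone; median 2.26, camera adjusted p = 2.65e-19; adjusted p = 0.0816 with an estimated correlation). Col5a1 was at 3.08 (SE 0.44) and Loxl2 at 2.26 (SE 0.31). Macrophage genes were higher in 7 of 16 (11 adjusted over the list alone; median 1.53, camera adjusted p = 1.02e-10; adjusted p = 0.135 with an estimated correlation). Adgre1 was at 2.76 (SE 0.32) and Cd68 at 2.41 (SE 0.29). Cytotoxic genes (1.60, camera adjusted p = 0.000254; adjusted p = 0.477 with an estimated correlation) had Ccl5 at 2.81 (SE 0.44) and Ncr1 at 2.85 (SE 0.60), the latter without a call in a fit of the 2 groups alone (2.84), in limma voom (2.53) or with the days covariate (2.64). With a filter of 1 CPM in 3 mice the cytotoxic median was 0.76.

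Wound keratinocyte genes were lower after AFL than after vismodegib in 7 of 20 (11 adjusted over the list alone; median -1.65, camera adjusted p = 0.000113; adjusted p = 0.446 with an estimated correlation). Sprr2d (-5.74, SE 0.81) and the antimicrobial peptide gene Defb3 (-8.15, SE 1.25) were lower and Plaur higher (2.99, SE 0.44). Itga5 was higher too, named after its values were seen. Il17a was lower (-6.64, SE 1.04, adjusted p = 0.00103) and Ccl3 higher (5.32, SE 1.00) within an inflammatory list that was not called (1.95, adjusted p = 0.139). The neutrophil list was not called (0.67, adjusted p = 0.77), and without AFL mouse 11 it was called lower (-0.83, adjusted p = 0.0332). Also called were endothelial (0.87, camera adjusted p = 0.00472; adjusted p = 0.783 with an estimated correlation) and erythroid (2.74, camera adjusted p = 0.00172; adjusted p = 0.201 with an estimated correlation) genes. Further calls were those of sebaceous gland (-1.2, camera adjusted p = 0.00304; adjusted p = 0.743 with an estimated correlation; Elovl3 -2.22) and heat shock (-0.61, camera adjusted p = 0.0013; adjusted p = 0.135 with an estimated correlation; Hspa1b -1.42) genes. Cell cycle (-0.49) and growing hair genes (-4.49) were called at a camera adjusted p of 0.0217 and an adjusted p = 0.811 with an estimated correlation. Without vismodegib mouse 6, the one in growing-hair phase, the growing hair median was 1.88. It was -7.62 without AFL mouse 11 and -2.83 under the replicate block, and the call ended with all libraries as replicates (-3.67), the hair covariate (0.42) and the days covariate (-2.85). Days ended the endothelial (0.69) and cell cycle calls (-0.20) as well and moved the sebaceous median to -1.85. The cell cycle call also ended with the hair covariate (-0.38) and all libraries as replicates (-0.28), and its median was -0.77 without AFL mouse 11. Library size alone gave -0.20 for the cell cycle and -0.40 for heat shock. Without AFL mouse 7 the endothelial (0.67), growing hair (-3.96) and cell cycle calls (-0.29) ended, the last also without vismodegib mouse 9 (-0.27). Elovl3 and Hspa1b lost their calls without AFL mouse 2 (-1.89 and -1.12) or 11 (-2.16 and -1.36) and in the fit of the 2 groups alone (-2.21 and -1.42). Without AFL mouse 11 Plaur was at 1.96 and Ccl3 at 2.73. The sebaceous median was -1.81 without AFL mouse 7 and -0.78 without vismodegib mouse 1. Median, mean and test differed in sign for the embryonic follicle (0.06, -0.16, up), p53 target (0.01, 0.02, down) and T cell lists (-0.26, 0.06, up), none of them called.

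The comparisons with healthy skin asked how far treated skin stood from skin without tumours. After AFL, Trp53 fell (-1.62), and Ptch1 (-0.57), Gli1 (-0.05), Gli2 (-0.17) and Hhip (0.97) did not pass. The Hedgehog list was not called (-0.26, adjusted p = 0.192). Gli1 was at 91.3 ± 53.6 CPM after AFL and 94.7 ± 32.2 in healthy skin. Of 1456 changed genes 1253 rose and 203 fell. Interferon genes rose in 24 of 26 (25 adjusted over the list alone; median 3.99, camera adjusted p = 6.61e-68, or 0.000865 with an estimated correlation), Mx1 by 5.22 (SE 0.40, adjusted p = 2.95e-06). Macrophage genes rose in 12 of 16 (15 adjusted over the list alone; median 1.96, camera adjusted p = 1.78e-18, or 0.0419 with an estimated correlation), Fcgr1 by 5.01 (SE 0.40). Wound keratinocyte genes rose in 13 of 20 (15 adjusted over the list alone; median 3.38, camera adjusted p = 2.35e-14; adjusted p = 0.0923 with an estimated correlation), Krt6b by 10.68 (SE 1.12) and Krt16 by 4.97 (SE 0.58). Matrix genes rose in 14 of 21 (20 adjusted over the list alone; median 1.72, camera adjusted p = 1.75e-17; adjusted p = 0.0543 with an estimated correlation), Mmp13 by 8.46 (SE 0.81). Growing hair genes were at -6.31 (camera adjusted p = 1.95e-09; adjusted p = 0.382 with an estimated correlation) with 2 falls, Dlx3 (-4.03, SE 1.14) and Foxn1 (-2.52, SE 0.76). Wnt targets were at -1.15 (camera adjusted p = 7.15e-05; adjusted p = 0.288 with an estimated correlation) with Tcf7 (-1.13, SE 0.27) and Notum (-2.36, SE 0.60) lower. The calls of Dlx3 and Foxn1 ended without any of the AFL mice (-4.37 to -3.78 and -2.85 to -2.25) or of healthy mice 10, 13 and 14, and that of Foxn1 also without healthy mouse 15. Those of Tcf7 and Notum ended without AFL mouse 11 (-0.97 and -2.09), Notum also without AFL mouse 2 (-2.13). Also called were the neutrophil (6.35) and inflammatory cytokine lists (5.01; for both, adjusted p = 0.178 with an estimated correlation), the cytotoxic (1.97) and erythroid lists (2.15; for both, adjusted p = 0.344 with an estimated correlation). Further calls were those of regulatory and checkpoint genes (1.09; adjusted p = 0.377 with an estimated correlation), mast cells (0.61; adjusted p = 0.327 with an estimated correlation), endothelium (0.84; adjusted p = 0.475 with an estimated correlation), melanocytes (-6.23; adjusted p = 0.382 with an estimated correlation) and muscle (-1.19; adjusted p = 0.52 with an estimated correlation). Without AFL mouse 11 the medians were 4.13 for neutrophil and 2.90 for inflammatory genes. The erythroid call ended without healthy mouse 16 (2.06) or AFL mouse 2 (1.56) or with all libraries as replicates (2.09) and the endothelial call without AFL mouse 7 (0.48). Leaving out AFL mouse 7 moved the muscle median to -2.45 and AFL mouse 11 to -0.75, the replicate block to -0.55 and the hair covariate to -3.34. The mast cell median was 0.30 without AFL mouse 2, 1.07 under the block and 0.38 with all 19 libraries as replicates, and the growing hair median was -9.66 without AFL mouse 11. The calls of Dlx3 and Foxn1 ended with library size alone (-4.10 and -2.58), that of Dlx3 also in limma voom (-3.70). That of Foxn1 ended with RLE scaling (-2.53), with either other filter (-2.54 and -2.55) and with 1 library per mouse (adjusted p = 0.0516). The growing-hair covariate, added after the data were seen, ended the calls of Dlx3 (-1.0), Foxn1 (-0.52), Tcf7 (-0.76) and Notum (-1.73). It ended those of the growing hair (0.16), Wnt target (-0.80), melanocyte (-1.11), cytotoxic (0.69), regulatory and checkpoint (0.12), mast cell (-0.05) and endothelial lists (0.26). With it the antigen presentation list was called lower (-0.28, adjusted p = 0.0317). The mean log2 CPM of growing-hair genes did not overlap between healthy (3.55 to 9.25) and AFL mice (-1.35 to 3.19). These losses therefore do not show hair phase to be the cause. The cytotoxic call also ended with a filter of 1 CPM in 3 mice (1.04, adjusted p = 0.0809). The p53 target median of 0.13 and mean of 0.10 went with a test that pointed down without a call.

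After vismodegib, Trp53 fell (-1.57) and Ptch1 (-0.43), Gli1 (-0.86), Gli2 (-0.53) and Hhip (-1.19) did not pass one by one. The Hedgehog list as a whole was below healthy skin (median -0.70, camera adjusted p = 0.0196; adjusted p = 0.61 with an estimated correlation). That list call ended without healthy mouse 14 (-0.67) or vismodegib mouse 1 (-0.56) or 9 (-0.44), and the median was -1.10 without vismodegib mouse 6. Of 1834 changed genes 1193 rose and 641 fell, or 590 and 895 with library size alone. Wound keratinocyte genes rose in 14 of 20 (16 adjusted over the list alone; median 4.43, camera adjusted p = 1.2e-26, or 0.0374 with an estimated correlation), Sprr2d by 11.29 (SE 0.81, adjusted p = 5.99e-07), Il1f6 by 7.71 (SE 0.63) and Krt16 131-fold (7.04, SE 0.62). Neutrophil genes rose in 9 of 10 (median 5.23, camera adjusted p = 2.8e-11; adjusted p = 0.298 with an estimated correlation), and Il17a had a ratio of 544 with a counting interval of 97.0 to 21542.9 (ratio 349 without vismodegib mouse 9). Differentiated keratinocyte genes rose in 5 of 16 (0.50, camera adjusted p = 0.00112; adjusted p = 0.573 with an estimated correlation), Casp14 by 2.53 (SE 0.32) and Krt1 by 3.44 (SE 0.58), with Krtdap, Klk7 and Hrnr named after their values were seen. Sebaceous genes rose as a list (1.03, camera adjusted p = 0.0301; adjusted p = 0.61 with an estimated correlation), Elovl3 by 2.83 (SE 0.43). The sebaceous call ended without healthy mouse 13 (0.90) or 14 (0.85) or vismodegib mouse 1 (0.52). Inflammatory cytokine genes (3.63; adjusted p = 0.318 with an estimated correlation), regulatory and checkpoint genes (0.87) and Wnt targets (-0.89; for both, adjusted p = 0.573 with an estimated correlation) were called as well. So were interferon (0.87) and growing hair genes (-1.80; for both, adjusted p = 0.61 with an estimated correlation). Calls of the cell cycle (0.60), macrophage (0.64), melanocyte (-1.72), fibroblast (-0.65), adipocyte (-1.03; for these, adjusted p = 0.61 with an estimated correlation) and muscle lists (-0.67; adjusted p = 0.696 with an estimated correlation) each ended without 1 or more single mice. Examples are healthy mouse 15 for the cell cycle (0.40), fibroblast (-0.54), adipocyte (-0.85) and muscle lists (-0.48) and healthy mouse 10 for the macrophage (0.42) and melanocyte lists (-1.68). Single mice moved the muscle median between -1.22 and -0.31, and without vismodegib mouse 6 the growing hair median was -8.01 and the melanocyte median -4.06. Without vismodegib mouse 9 the Wnt target median was -0.59 and the macrophage call ended (0.17). Library size alone ended the melanocyte (-1.86), adipocyte (-1.36) and muscle calls (-1.11). It moved the medians of cell cycle (0.32), differentiated keratinocyte (0.22), macrophage (0.18) and fibroblast genes (-1.0). The replicate block ended the adipocyte (-0.43) and muscle calls (-0.15) and moved the growing hair median to -3.49. The hair covariate moved the fibroblast (-0.99), adipocyte (-2.08) and muscle medians (-2.30). It ended the calls of the Hedgehog (-0.58), Wnt target (-0.33), differentiated keratinocyte (0.02) and sebaceous lists (0.08). It ended those of the macrophage (0.10), regulatory and checkpoint (0.59), interferon (0.44), melanocyte (0.38) and growing hair lists (-0.26) too. Apart from vismodegib mouse 6 (8.13), the vismodegib mice had growing-hair scores of -0.11 to 0.62, below every healthy mouse (3.55 to 9.25). The calls lost with the covariate therefore do not show hair phase to be the cause. Median, mean and test differed in sign for the cytotoxic (0.07, 0.16, down), matrix (-0.41, 0.56, down) and immediate early lists (0.02, -0.16, down), none of them called.

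**Figure D3:**
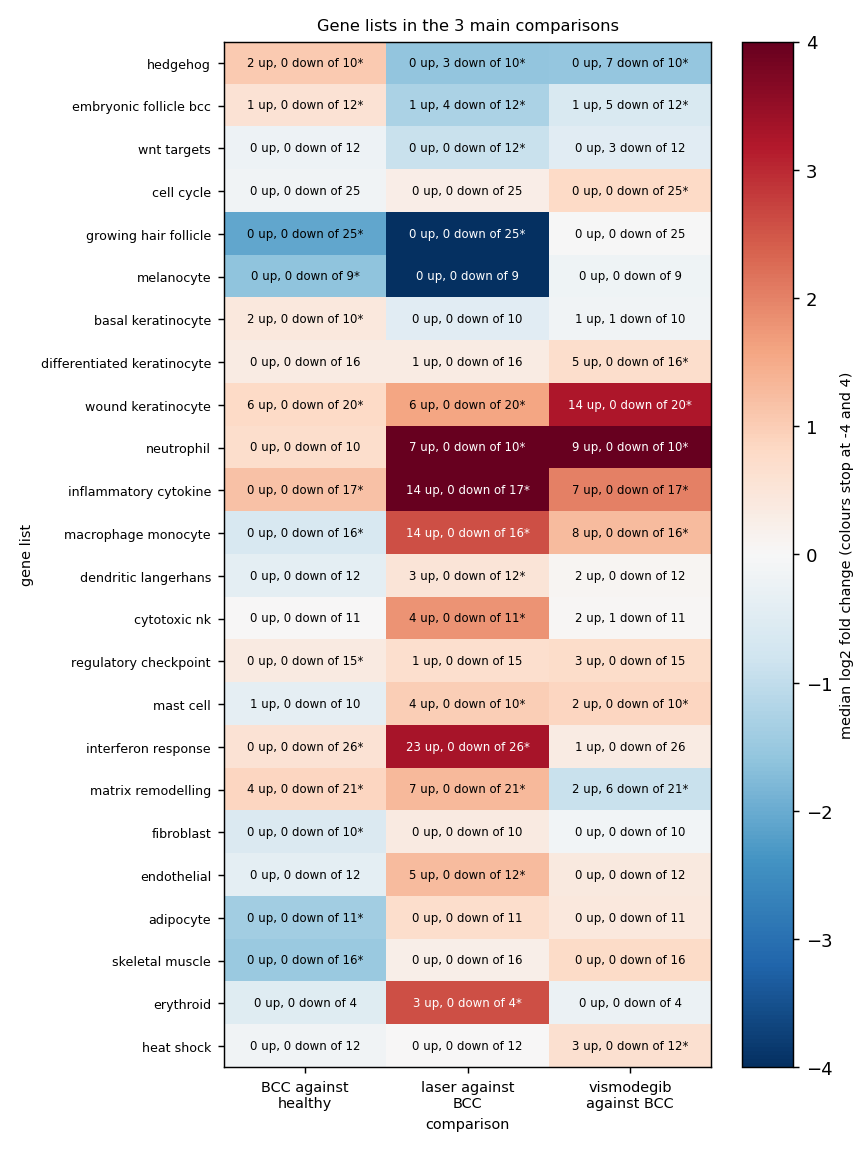
Median log2 fold change of the 24 lists called in at least 1 of the 3 main comparisons, by comparison, with the numbers of genes that rose and fell out of those tested in each cell and a star where camera gave an adjusted p under 0.05; colours stop at -4 and 4. The interferon median is 3.31 after AFL against BCC and 0.32 after vismodegib against BCC, and the wound keratinocyte median is 1.58 and 3.25.

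The treatment effects were set side by side across 15760 genes, which are not independent replicates and share the same BCC mice. Log2 fold changes of AFL and of vismodegib against BCC correlated with r = 0.561 (rho = 0.524), against 0.454 in simulated data without effects. With the BCC mice split between both comparisons the mean r was 0.376, with a range of 0.178 to 0.547 over the 6 splits. The covariance of both effects with all mice was 0.481, and 0.114 in the simulated data, a difference of 0.367. The simulated genes were drawn independently of one another, so these data lack variation that genes share, such as hair phase. Differences from simulated values, here and below, therefore do not by themselves show a relation between the effects. Both treatments raised 294 genes, where independent lists would share 77.2. Split controls gave a median of 61, where independent lists of their size would share 13.6. Both lowered 201, where independent lists would share 23.4, and split controls gave 63.5 with 4.06 for independent lists. Of the 420 genes that rose in BCC, 305 (72.6%) fell after vismodegib and 94 (22.4%) fell after AFL. Independent lists would share 37.8 and 6.93, and split controls gave medians of 159 and 21 with 12.3 and 1.35 for independent lists. Effects of BCC against healthy skin had r = -0.249 with those of vismodegib and -0.0637 with those of AFL, and simulated data without effects gave -0.521 and -0.489. The covariances were -0.187 and -0.0458 with -0.115 in the simulated data, differences of -0.0719 and 0.0694.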

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

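The 3 tests of the keratinocyte genes of barrier repair after vismodegib given here were chosen after their values were seen. For the named genes that are reported and every list, each group of 4 or 5 mice was searched for a mouse far from the others, measured as its gap to the nearest mouse divided by the range of the group. Of 606 groups 41 passed the limit, 33 for genes and 8 for lists, and chance alone marks about 1 in 20 groups, or 30.3 here. The AFL group, with 3 mice, was not searched.

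Healthy mouse 15 had the lowest Hedgehog expression of the healthy mice, with ratios of 0.817 for Ptch1, 0.797 for Gli1 and 0.732 for the Hedgehog list. It was also low for the heat shock gene Hspa8 (0.754), and high for the Wnt inhibitor gene Notum (0.766) and for Il17a (1), which was near the floor in healthy skin. Its growing-hair score was 6.57, within the range of 3.55 to 9.25 of the healthy mice. Healthy mouse 10 was low for the matrix genes Loxl2 (0.881) and Col1a1 (0.764) and high for the sebaceous gene Elovl3 (0.724). Healthy mouse 14 was high for the haemoglobin gene Hba-a1 (0.804) and the immediate early list (0.78) and low for Ncr1 (0.759). Healthy mouse 16 was high for Mymk (0.919) and Serpinb3d (1), both near the floor in healthy skin.

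BCC mouse 3, whose skin expressed growing-hair genes, stood out for pigment cell genes, which are active in growing follicles. Ratios were 0.909 for Dct, 0.899 for Tyr, 0.88 for Mlana and 0.887 for the melanocyte list, with 0.854 for the hair matrix factor Msx2, all high. The same mouse was low for the macrophage list (0.867), the dendritic cell list (0.883), the checkpoint receptor gene Tigit (0.914), Entpd1 (0.85) and Sprr2b (0.882). BCC mouse 5 was high for the interferon-stimulated genes Mx1 (0.877) and Xaf1 (0.963). BCC mouse 8 was high for Cd74 of antigen presentation (0.892) and for the basal keratinocyte list (0.842). No cause of these deviations was tested.

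Among vismodegib mice, mouse 9 was high for Klk7 (0.947), Il10 (0.941), Il17a (0.928), Hspd1 (0.877), Pcna (0.875), Cxcl2 (0.832), Mmp12 (0.832) and the heat shock list (0.845), and low for Oas3 (0.948). Mouse 6 was high for the growing-hair list (0.911) and low for Entpd1 (0.881) and Cd28 (0.831), and mouse 12 was high for Ccl5 (0.837).

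Because mouse 9 stood out so often, the rise of wound keratinocyte genes after vismodegib, with a median of 3.25, was tested further. Without mouse 9 the median was 2.891 (camera adjusted p = 7.66e-16, bootstrap spread of the median 0.912). The mean log2 CPM of the list was 7.51 to 8.43 in the other vismodegib mice and 4.23 to 5.38 in the BCC mice. These values argue against mouse 9 as the whole source. The bootstrap spreads given here resample genes and leave out the spread between mice. Library size alone, which shifted all genes down, left a median of 2.786 (camera adjusted p = 7.68e-22, spread 0.990), so scaling does not account for the rise alone. Growing-hair expression as a covariate gave 3.431 (camera adjusted p = 1.62e-15, spread 1.02). Apart from mouse 6, growing-hair scores of vismodegib mice (-0.11 to 0.62) lay below those of all BCC mice (0.64 to 8.11). The covariate therefore cannot decide on hair phase. In growing-hair phase, the mean log2 CPM of the wound list was 7.51 in vismodegib mouse 6 and 4.65 in BCC mouse 3. A candidate explanation is a reaction of the epidermis to the repeated topical treatment. Whether the drug or its vehicle set it off stays open, since no vehicle group is among the samples, and with an estimated correlation between genes the list had an adjusted p of 0.229.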

How the results depend on the processing

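The covariate of growing-hair expression and the fit without BCC mouse 3 and vismodegib mouse 6 were chosen after the data were seen, and the other alternatives before. Comparisons are given in the order BCC against healthy, AFL against BCC, vismodegib against BCC, AFL against vismodegib, AFL against healthy and vismodegib against healthy, with main counts of 445, 1221, 2684, 1442, 1456 and 1834 changed genes.

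An adjusted p under 0.01 left 231, 582, 889, 541, 801 and 556 genes, by construction. DESeq2 called 936, 2001, 2509, 2487 and 3164 genes, all but vismodegib against BCC, where its count was within 1.5 times. All 19 libraries as replicates, which count 3 mice more than once, gave 2068 (AFL against BCC), 2612 (AFL against vismodegib), 3058 (AFL against healthy) and 3425 (vismodegib against healthy). Fits of the 2 groups alone gave 984 (vismodegib against BCC), 642 (AFL against vismodegib), 2874 (AFL against healthy) and 1121 (vismodegib against healthy). Days since induction as a covariate left 715 genes for AFL and 1535 for vismodegib against BCC. Growing-hair expression as a covariate gave 983 in BCC against healthy. Without BCC mouse 3 and vismodegib mouse 6 the counts were 1337 (BCC against healthy), 2374 (AFL against healthy) and 3985 (vismodegib against healthy). Apart from the stricter p and the repeated mice, the cause was not tested.

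Leaving out 1 mouse gave 265 to 798, 597 to 1698, 1503 to 3418, 732 to 1832, 799 to 1883 and 951 to 3490 genes. In BCC against healthy the count was 285 without healthy mouse 13, 278 without 14, 265 without BCC mouse 4 and 798 without BCC mouse 3. In AFL against BCC it was 597 without AFL mouse 11. In vismodegib against BCC it was 1679 without BCC mouse 4, 1503 without BCC mouse 8 and 1762 without vismodegib mouse 9. In AFL against vismodegib it was 732 and 847 without AFL mice 2 and 11 and 830 without vismodegib mouse 1. In AFL against healthy it was 799 without AFL mouse 11. In vismodegib against healthy it was 1062, 1099, 993 and 984 without healthy mice 13, 14, 15 and 16, 951 without vismodegib mouse 9 and 3490 without vismodegib mouse 6.

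The replicate block moved the count past 1.5 times in vismodegib against healthy alone (1040), and gave 298, 1236, 2175, 1549 and 1565 in the others. The numbers do not pair the mice. Of 21 same-number pairs 7 had a correlation of their deviations over 0.1, with a median of -0.166, and 1 mouse correlated best with its own number. Of the values of named genes the block left 298 on the same side of the threshold, 29 lost and 4 gained a call, and of list values 169, 3 and 8.

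The correlation of the effects of both treatments was 0.3762 on average with the BCC mice split between the comparisons (0.561 with all). That of BCC against healthy with AFL was 0.03605 on average (-0.0637 with all). Over the splits the latter ranged from -0.299 to 0.365, so its sign is not settled. The split removes shared mice and leaves fewer of them. Reversed list medians or tests were those of growing hair in BCC against healthy (-0.1629), antigen presentation in AFL against healthy (-0.2773) and melanocytes in vismodegib against healthy (0.3795) with the hair covariate, growing hair in AFL against vismodegib without vismodegib mouse 6 (1.878, other single mice down to -7.62), and neutrophil genes in AFL against vismodegib without AFL mouse 11 (-0.8298, other single mice up to 2.042). The covariate is built from the growing hair list itself, and the cause of the others was not tested. RLE scaling kept 327 named-gene values on their side of the threshold, with 1 lost and 3 gained, library size alone 292, with 32 lost and 7 gained, and DESeq2 291, with 0 lost and 40 gained. Over 180 list tests, which include lists without a call, camera with an estimated correlation ended 76 calls and fry 39. In BCC against healthy both ended every list call. With an estimated correlation, calls held for the interferon list in each comparison of AFL and the macrophage list in AFL against BCC and AFL against healthy. The wound keratinocyte call in vismodegib against healthy held too, and no other. With 3 to 5 mice per group, changes of 2-fold were mostly out of reach in simulated data, so a gene without a call is not shown to be unchanged.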

Other observations

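The tests of the muscle genes and of the basal keratinocyte genes, and the gene groups of the first paragraphs, were chosen after their values were seen, and the splits of mice and the induction time test of the Hedgehog genes before. The growing-hair covariate was chosen after the data were seen, before its effect on the Hedgehog genes was. After AFL, 12 of 14 genes of regenerating muscle rose against BCC. Besides Actc1, Myh3 and Mymk these included the myogenic factor Myog (5.12, adjusted p = 0.004), the embryonic light chain Myl4 (6.01, adjusted p = 7.9e-05) and the perinatal myosin Myh8 (6.34), while Myod1 did not pass (3.11, adjusted p = 0.072). After vismodegib, 3 of these genes rose and Ncam1 fell. Of 14 genes of the interleukin 17 axis, 11 rose against BCC after vismodegib and 0 after AFL, while against healthy skin 11 and 6 rose. Il17f (6.80, adjusted p = 0.00028) and the response genes Zc3h12a (2.57) and Nfkbiz (1.84) were among them. In the direct comparison of AFL with vismodegib, 9 of the 14 muscle genes were higher after AFL and 6 of the 14 interleukin 17 genes lower. All 9 distinct Sprr2 measurements, 6 Lce3 genes and 3 Serpinb3 genes rose against BCC after vismodegib and 0 of each after AFL, where medians were 1.5, 1.68 and 0.99. Against healthy skin 7, 5 and 2 of them rose after AFL, and in the direct comparison 6, 3 and 2 were lower after AFL than after vismodegib. Reads are shared among family members, and Sprr2a1 and Sprr2a2 hold identical counts.

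Some changed genes are best known from other tissues, and no test was made of whether there were more of them than chance would give. Of 7 genes of eye development 5 rose against healthy skin, including Vax1 (7.14) and Cryaa (4.99, adjusted p = 0.00042), and 5 fell after vismodegib and 3 after AFL. Of 9 cartilage and bone genes 3 rose, Col2a1 (5.11, adjusted p = 0.00014), Col9a2 (4.78) and Col9a3 (2.29), and these 3 fell after each treatment. Sost and Col11a1 also fell after vismodegib. After AFL, Sost and Acan passed too, with calls that ended without single mice. The cell cycle inhibitor locus Cdkn2a, which is raised where p53 is lost, rose by 5.84 (adjusted p = 0.00014), from 0.409 to 24.0 CPM. It fell after vismodegib (-2.92, adjusted p = 0.004; 3.19 CPM) and did not pass after AFL (-1.30, adjusted p = 0.24; 9.75 CPM).

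In each comparison the real grouping of the mice gave more changed genes than every other split counted. With 35 splits the smallest possible share is 2.86%, and the comparisons share mice, so chance in the grouping is not excluded. Of the splits of the mice of both groups into the same sizes, 1 of 100 gave as many as the 445 genes of BCC against healthy, the real one itself, and the highest other gave 130. For AFL against BCC it was 1 of 35 (1221, highest other 457), for vismodegib against BCC 1 of 35 (2684, highest other 742) and for AFL against vismodegib 1 of 35 (1442, highest other 636). For AFL against healthy it was 1 of 56 (1456, highest other 420) and for vismodegib against healthy 1 of 100 (1834, highest other 878).

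Hedgehog genes were lower after AFL, with a list median of -1.57. A smaller share of keratinocytes would lower basal keratinocyte genes alike, but their median was -0.44. The difference of 1.132 had p = 0.00068 in a permutation of the members. That permutation treats genes of the same mice as independent and leaves out the spread between mice. It therefore cannot rule out a smaller share of keratinocytes. With growing-hair expression as a covariate the median was -1.238 (camera adjusted p = 6.22e-06, spread over genes 0.120). Growing-hair scores were -0.18, -1.35 and 3.19 in AFL mice 2, 7 and 11 and 0.64 to 8.11 in the BCC mice. The AFL scores lie partly below all BCC scores, so this value rests in part on extrapolation and cannot decide on hair phase. With days since induction as a covariate the Hedgehog median was -1.23 (camera adjusted p = 0.0136, spread over genes 0.194). Days did not overlap between AFL (80 to 126) and BCC mice (130 to 144), so this value rests on extrapolation and cannot decide on induction time. A loss of tumour cells or a lower signal within them may each lie behind the lower Hedgehog genes. Hair phase, induction time, age, the lack of a sham group and the lost list call with an estimated correlation (adjusted p = 0.2) leave the cause open. The single-gene calls of Hhip and Gli2 ended with the days covariate, where Hhip went from -2.549 to -1.56 and Gli2 from -1.449 to -1.496.

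Genes of regenerating muscle rose after AFL with a median of 4.52. The regenerating genes were grouped after their values were seen. More muscle in the laser-treated samples would raise the adult list, fixed before, about as much, but its median was 0.247. The standard error of the difference of its mean score between the groups was 1.19, and the SD among AFL mice was 1.95. The regenerating median stayed between 3.891 and 4.84 without each AFL mouse (spread 0.860), so 1 mouse did not account for it. Repair of the thin muscle under the skin after heat injury may explain the pattern, as a hypothesis found and tested on the same data. Muscle histology or untreated skin beside the laser field were not used here.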
